A study of Mus musculus with 6 samples.

How the data were processed

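Gene expression was measured by RNA sequencing in 6 libraries of mouse bone marrow-derived macrophages from wild-type animals, 3 controls and 3 treated with LPS and PA-BSA. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol and taken on where its integrity number passed the submitters' limit, poly(A) RNA was purified on oligo(dT) beads, fragmented and reverse transcribed, the second strand was marked with dUTP and removed, and the libraries were sequenced as read pairs on an Illumina NovaSeq. Selection of poly(A) RNA leaves out RNA without a tail, and PCR during library preparation can favour fragments by their GC content, so FPKM of GC-rich and GC-poor genes can shift between libraries.

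The authors deposited a table of 29957 genes with FPKM values, 1 column per library, so replicates were not pooled. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and the genome build mm10, with no role or order, and the annotation behind the table is not given in the sources used here. Beside the FPKM values, per the file headers, the authors gave a fold change (fc), its log2, a p-value and a q-value and a mark of significance. Their fold change equals the ratio of the mean FPKM of the groups in all 23889 rows where both means are above 0, and the marked genes all have a q-value under 0.05 and an absolute log2 fold change of at least 1. Which tool gave these p-values is not given in the sources used here. No column of per-sample values was left unassigned. FPKM is relative to the total of each library, so a few very abundant transcripts that rise or fall move all others a little the other way. No 2 libraries held identical values.

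The table holds no counts, so the test planned for FPKM was used: limma with a trend of the variance on the mean, on log2(FPKM + 1), for the 11364 genes at 1 FPKM or more in at least 3 of the 6 libraries, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and levels are given as mean FPKM ± SD. No count model was fitted. For single values per library, exact permutation tests of 3 against 3 were used, two-sided, whose smallest p is 0.1. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated data of 11364 genes, limma recovered 22.4% of genes changed by 0.5 and 68.7% of those changed by 1 on the log2 scale. Of those changed by 2 it recovered 92.4%, with 5 false calls among 11164 unchanged genes. The simulated noise was independent between genes, unlike in these libraries, which share departures across genes (set out further on). Far fewer genes were changed than were called in the data, which makes the adjusted threshold stricter. These shares and false calls therefore do not carry over to the data.

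FPKM of a gene with 1 transcript falls in steps of 1 fragment at low values. These steps, searched with a tolerance of 0.5%, gave the depth of each library, between 13.9 and 21.1 M (mega) fragments. In a transcript of 1 kb, 1 fragment was worth 0.0474 to 0.0722 FPKM, so values near the filter at 1 FPKM rest on few fragments in short transcripts. These depths cover counting error only, as PCR copies are not independent molecules.

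Gene IDs were matched to GENCODE M21 (mm10), where 29871 of 29957 were found. Coordinates, biotypes, exonic length and the GC content of transcripts come from it. Of the symbols, 55 stand on more than 1 row, and the row with the highest mean was used. Genes with near-identical copies or many pseudogenes can share reads, depending on how the authors' tools split them.

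Before the data were examined, 33 gene lists with 604 members were fixed from textbook knowledge of macrophage activation, lipid metabolism, stress responses and other cell types in marrow, of which 594 were found in the table (Ddx58 stands for Rigi and Ero1l for Ero1a). They cover the inflammasome and pyroptosis, the NF-kB and TLR primary response, type I interferon, negative feedback of TLR signalling, the TLR4 pathway, alternative activation, lipid uptake and PPAR targets, mitochondrial fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, cholesterol efflux and LXR targets, ceramide, the integrated stress response, ER chaperones, NRF2, heat shock, glycolysis and hypoxia, oxidative phosphorylation, lysosome, autophagy, apoptosis and necroptosis, class I and class II presentation, the cell cycle, macrophage identity, mitochondrially encoded genes, and markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells and basophils, stromal cells and erythroid cells. Lists with at least 2 tested members (29) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, Benjamini-Hochberg adjusted over the lists, with fry beside it. The rule for named genes, fixed at the same time, took the 10 largest rises and 10 largest falls past the threshold without overlap of the groups and with at least 5 FPKM in the higher group (unnamed loci left out), the 2 members of each list with the largest absolute log2 fold change past the threshold (or the one with the smallest p), and always Nlrp3, Pycard, Casp1, Gsdmd, Il1b, Il18, Il1a, Tnf, Il6, Nos2, Cd36, Plin2 and Cpt1a, which gave 84 genes, 2 of which are not reported here. Names outside the rule are marked as chosen after their values were seen.

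Analyses chosen before the data were examined were median-ratio rescaling and quantile normalization, no variance trend, no filter, a filter at a mean of 5 FPKM, pseudocounts of 0.1 and 5, a threshold of 1 on the absolute log2 fold change, an adjusted p under 0.01, the replicate number as a block, each library left out in turn, and shares without the 10 most abundant genes. Added after seeing the data were the removal of each library's smooth trend (lowess, span 0.3) on GC content and exonic length, a term for 2 sets of libraries that differ in transcripts of other tissues, and each set alone. The pathway terms in the closing part are the KEGG annotation in the deposited table, for 289 terms with at least 10 tested genes. Those meant for a table of counts (other size factors and a count test) were not run, as the table holds none.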

Results

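RNA was sequenced from mouse bone marrow-derived macrophages, which are macrophages grown in culture from marrow cells. The 6 libraries fall into 2 groups of 3. The first group was the control, and the second received lipopolysaccharide (LPS, a component of the bacterial cell wall sensed by the receptor TLR4) followed by PA-BSA, a free fatty acid preparation. The labels give no dose or time, and do not say whether the control cells received LPS or the BSA carrier. No group with LPS alone was analysed here, so the effects of LPS and of PA-BSA were measured together. Nothing in the labels says that the 3 samples of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. The deposited table gives FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library). From the smallest steps between low FPKM values, the libraries held about 21.1, 15.9 and 13.9 M (mega) fragments in controls 1 to 3 and 18.8, 14.3 and 17.1 M in LPS+PA 1 to 3. The mean depth was 17.0 ± 3.74 M fragments (SD, n = 3) in controls and 16.7 ± 2.26 M fragments (SD, n = 3) after LPS and PA-BSA (exact permutation test, two-sided p = 1, where 0.1 is the smallest p that 3 against 3 allows).

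The study asked how macrophages respond when a free fatty acid takes the place of ATP as the second signal of the Nlrp3 inflammasome, the protein complex that activates caspase-1, with LPS as the first signal. After LPS and PA-BSA the macrophages held far more mRNA of inflammatory and interferon-induced genes. Among the largest rises on the log2(FPKM + 1) scale were those of Il1a and Il1b, the genes of the interleukin-1 cytokines, from 2.43 ± 1.81 to 329 ± 4.63 FPKM and from 1.77 ± 1.30 to 201 ± 20.5 FPKM (SD, n = 3 per group). Of the gene lists fixed beforehand, 16 of 21 tested genes of endoplasmic reticulum (ER) chaperones, 13 of 18 of the antioxidant response and 12 of 14 of class I antigen presentation rose as well. Of 21 tested genes of cholesterol synthesis and uptake 19 fell, as did 11 of 14 of fatty acid synthesis, 25 of 26 of the cell cycle, 15 of 18 of macrophage identity and 8 of 14 of alternative activation. In the last list, Mrc1 (the mannose receptor) went from 105 ± 7.84 to 3.32 ± 0.342 FPKM. These lists passed camera with a preset correlation between genes, and no list passed with an estimated one. Of 11364 genes tested with limma on log2(FPKM + 1), 2523 were higher and 3736 were lower in LPS+PA at a Benjamini-Hochberg adjusted p under 0.05. Of these, 756 and 1237 changed by at least 1 on the log2 scale. In 63.2% of the tested genes the 3 values of one group lay wholly above those of the other, where chance gives 10% for a single gene. Genes of the same libraries vary together, so the share over all genes can differ from 10% by chance, and 63.2% against 10% does not measure chance.

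The 10 genes past the threshold with the largest positive log2 fold changes and at least 5 FPKM were Il1a, Il1b, Ms4a4c, Clec4e, Ptgs2, Slfn4, Serpinb2, Cxcl10, Cxcl2 and Cfb. Their log2 fold changes ran from 5.68 for Cfb, the complement factor B gene, to 6.71 for Il1a. Their order differed between libraries: within control 3, LPS+PA 1 and LPS+PA 2 the log2 fold changes were 5.90 for Il1a and 5.59 for Il1b, below Ms4a4c (6.12) and Cxcl10 (5.98). Clec4e, which encodes the receptor Mincle, rose from 12.3 ± 4.42 to 919 ± 38.1 FPKM. Ptgs2, the inducible cyclooxygenase, rose from 3.07 ± 0.746 to 269 ± 10.98 FPKM, and Serpinb2, plasminogen activator inhibitor type 2, from 0.921 ± 0.557 to 119 ± 13.4 FPKM. Ms4a4c and Slfn4 belong to families of similar genes that can share reads, and their levels are uncertain to that extent. The 10 with the largest falls were Mrc1, Ighm, Slc9a9, Hpgd, Stab1, Gas6, Trav13-4-dv7, Acta2, Ccn5 and Rab3il1, from a log2 fold change of -4.61 for Mrc1 to -3.59 for Rab3il1. Slc9a9, a sodium and proton exchanger of endosomes, fell from 26.2 ± 1.04 to 0.336 ± 0.0518 FPKM. Hpgd, the enzyme that breaks down prostaglandins, fell from 20.05 ± 1.66 to 0.405 ± 0.177 FPKM. Gas6, a ligand of the receptors that take up dying cells, fell from 266 ± 54.2 to 18.1 ± 2.70 FPKM, and Acta2, smooth muscle actin, from 217 ± 14.1 to 16.5 ± 1.67 FPKM (SD, n = 3 per group throughout).

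Among 20 genes of the inflammasome and of pyroptosis (the lytic cell death that it triggers), 12 rose and 5 fell, with the same counts adjusted over the list alone. Nlrp3, the sensor, rose from 7.97 ± 0.203 to 44.3 ± 3.88 FPKM (SD, n = 3; log2 fold change 2.33, SE 0.0856, limma adjusted p = 5.03e-06). Casp1, the protease of the complex, rose from 30.3 ± 3.63 to 78.1 ± 5.77 FPKM, and Gsdmd, the pore-forming substrate, from 27.2 ± 2.12 to 40.3 ± 2.76 FPKM. Pycard, the adaptor ASC, fell from 8.73 ± 0.577 to 4.29 ± 0.178 FPKM (log2 fold change -0.88, SE 0.0815, limma adjusted p = 0.000199). The other 4 members that fell, named after their values were seen, were Nlrp1b, Txnip, P2rx7 and Nek7. P2rx7, the channel through which ATP acts as a second signal, went from 16.1 to 6.50 FPKM, and Nek7, which binds Nlrp3, from 17.1 to 11.6 FPKM. Il18 was at 2.22 ± 0.308 FPKM in controls and 3.49 ± 0.568 FPKM after LPS and PA-BSA (limma adjusted p = 0.0190). Its call ended without LPS+PA 2 (log2 fold change 0.44), without LPS+PA 3 (0.41) and with the replicate block (0.48). It also ended when each library's trend on transcript GC content and length was removed (0.27, limma adjusted p = 0.200). As a group the list was higher than other genes (camera adjusted p = 0.0111 with a preset correlation of 0.01, adjusted p = 0.289 with an estimated correlation), and after removing the GC trend it no longer passed (camera adjusted p = 0.0542), with 13 higher and 5 lower and a median log2 fold change of 0.39. Before that removal its median was 0.50. In mm10, Nlrp3 lies on chromosome 11 at 59541568 to 59566956, Il1b on chromosome 2 at 129364570 to 129371139, Il1a on chromosome 2 at 129299610 to 129309972, Casp1 on chromosome 9 at 5298517 to 5307265, Pycard on chromosome 7 at 127989708 to 127993867 and Gsdmd on chromosome 15 at 75862327 to 75867408. Each is annotated as a protein-coding gene, and each FPKM value is for the whole gene.

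**Figure D1:**
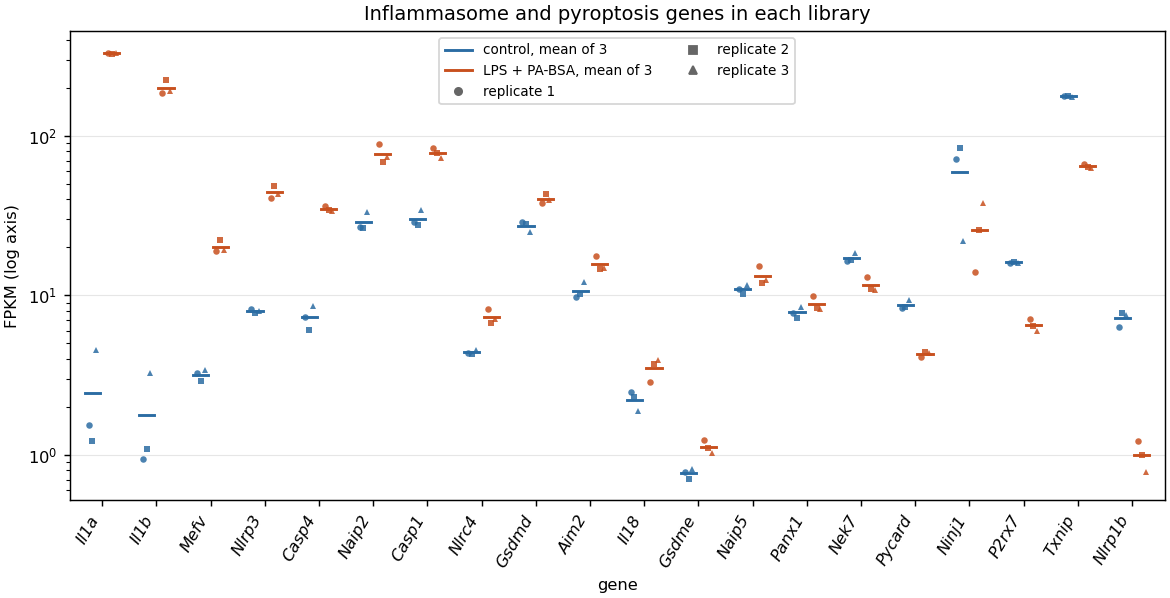
FPKM on a log axis of the 20 inflammasome and pyroptosis genes in each of the 6 libraries, with 1 point per library (circle, square and triangle for replicates 1 to 3) and a bar at the mean of each group of 3. Il1a and Il1b rose from below 5 FPKM to above 100, Nlrp3 from 7.97 to 44.3, and Pycard fell from 8.73 to 4.29 FPKM.

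All 29 tested genes of the type I interferon response rose, and of 33 tested genes of the NF-kB and TLR primary response 28 rose and 1 fell, with the same counts adjusted over the list alone. Cxcl10, a chemokine, rose from 3.40 ± 0.0645 to 279 ± 49.2 FPKM, and Rsad2, the antiviral protein viperin, from 12.8 ± 1.93 to 685 ± 41.7 FPKM (SD, n = 3 per group). Tnf rose from 21.1 ± 2.59 to 245 ± 43.9 FPKM, Il6 from 0.537 ± 0.252 to 46.0 ± 3.37 FPKM, Cxcl2 from 2.18 ± 1.25 to 172 ± 18.1 FPKM and Nos2, the inducible nitric oxide synthase, from 10.2 ± 4.42 to 211 ± 27.3 FPKM. The member that fell was Nfkbiz (28.2 to 21.3 FPKM, named after its value was seen). Median log2 fold changes were 3.96 for the interferon list (3.90 within the libraries control 1, control 2 and LPS+PA 3, and 4.08 within control 3, LPS+PA 1 and LPS+PA 2, the 2 sets defined further on) and 2.68 for the NF-kB list (2.70 and 2.84 within the sets). Both lists were higher than other genes (camera adjusted p = 2.32e-21 and 3.35e-15), and both had an adjusted p = 0.0812 with an estimated correlation. Of 10 tested genes of negative feedback, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.000138, adjusted p = 0.0812 with an estimated correlation). Acod1, which makes itaconate, rose from 42.0 ± 2.84 to 1368 ± 132 FPKM and Il1rn, the antagonist of the interleukin-1 receptor, from 11.6 ± 1.08 to 292 ± 8.25 FPKM. Il10, named after its values were seen, was at 3.27 FPKM in controls and 3.33 FPKM after LPS and PA-BSA. Of 21 tested genes of the TLR4 receptor pathway, 7 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.0268, adjusted p = 0.148 with an estimated correlation). Tlr2 went from 41.7 ± 1.84 to 122.8 ± 6.45 FPKM and Traf6 from 4.14 ± 0.323 to 12.6 ± 1.37 FPKM. This list did not pass after quantile normalization (camera adjusted p = 0.0944). In it 12 rose and 2 fell after each library's trend on transcript GC content and length was removed (camera adjusted p = 0.00872).

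**Figure D2:**
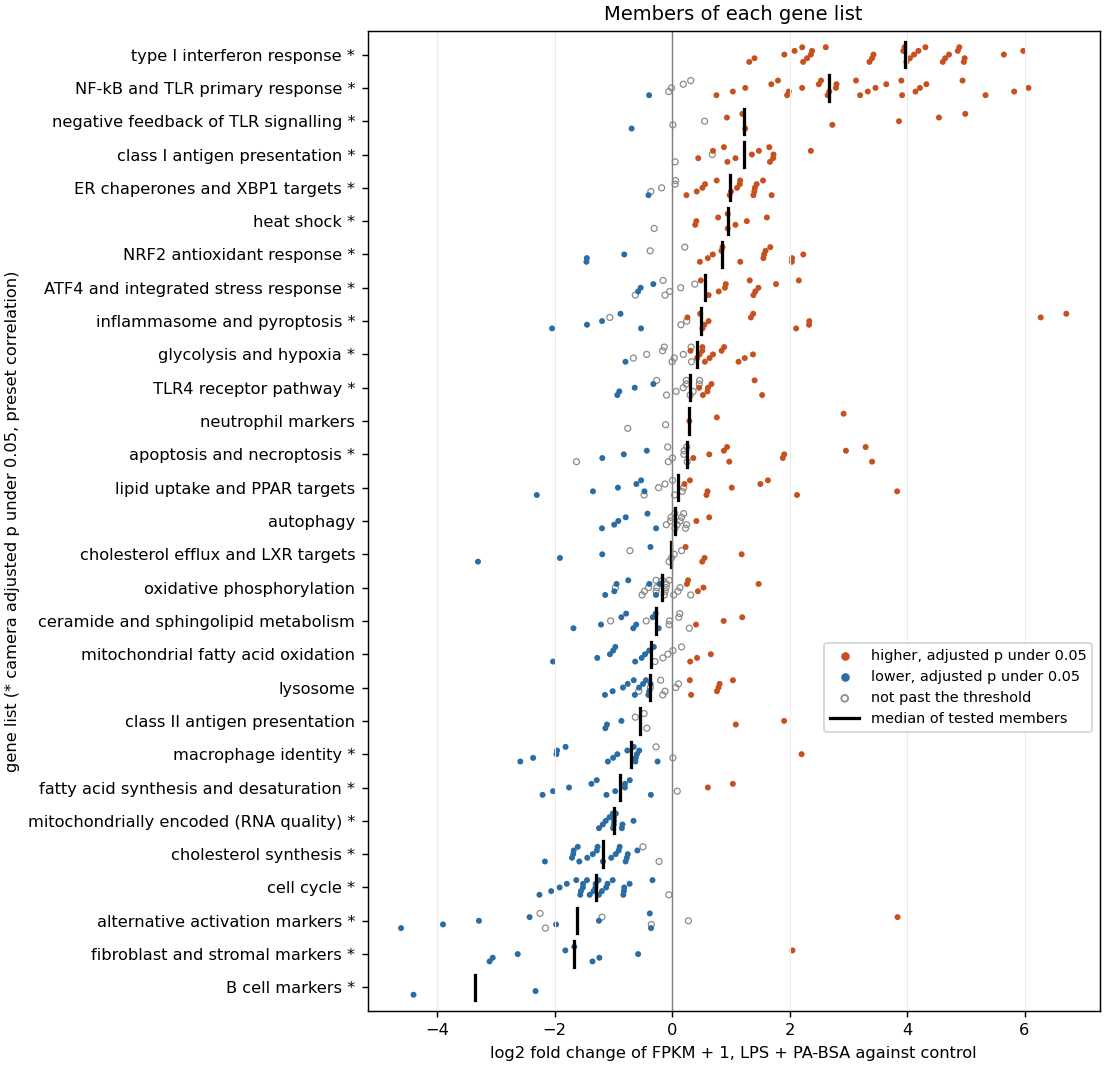
Log2 fold change of FPKM + 1 (LPS + PA-BSA against control) of each tested member of the 29 gene lists with at least 2 tested members, 1 point per gene and a bar at the median, with lists ordered by their median. Filled points passed an adjusted p under 0.05 in limma and open points did not. Medians ran from -3.36 for the B cell markers, which had 2 tested members, to 3.96 for the interferon response, and the 20 starred lists passed camera with the preset correlation but none passed with an estimated one.

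Of 14 tested markers of alternative activation, 8 fell and 1 rose, and of 18 macrophage identity genes 15 fell and 1 rose, with the same counts adjusted over the list alone. Stab1, a scavenger receptor, fell from 121 ± 54.2 to 6.54 ± 1.10 FPKM. C1qc, a chain of complement C1q, fell from 147 ± 69.0 to 23.4 ± 11.8 FPKM (SD, n = 3 per group). The members that rose, named after their values were seen, were the chemokine Ccl22 (0.167 to 15.8 FPKM) and the high-affinity IgG receptor Fcgr1 (37.5 to 176 FPKM). Adgre1, the gene of the macrophage marker F4/80 and named after its values were seen, was at 1400 FPKM in controls and 1417 FPKM after LPS and PA-BSA. Camera gave an adjusted p = 0.0268 for alternative activation and 0.00131 for macrophage identity, and with an estimated correlation the adjusted p = 0.335 and 0.0863. The alternative activation list did not pass within control 3, LPS+PA 1 and LPS+PA 2 alone (median log2 fold change -0.42, camera adjusted p = 0.107). All 13 mitochondrially encoded genes fell too, as set out further on. Of 14 genes of class I antigen presentation 12 rose and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 6.14e-06, adjusted p = 0.242 with an estimated correlation). Psme2, a proteasome activator subunit with a close copy that can share its reads, rose from 35.1 ± 3.26 to 185 ± 21.9 FPKM and the peptide transporter Tap1 from 7.43 ± 2.31 to 26.6 ± 6.08 FPKM. Of 8 tested class II genes 2 rose and 3 fell, the same adjusted over the list alone. The costimulatory gene Cd86 rose from 8.44 ± 0.854 to 34.4 ± 2.58 FPKM, and H2-DMb1 was at 12.0 ± 5.35 and 4.68 ± 1.66 FPKM (limma adjusted p = 0.0412), a call lost without any of 5 single libraries, where its log2 fold change ran from -1.52 to -0.87 over all 6 libraries left out in turn. The class II list had a median of -0.55 while camera placed it on the higher side (adjusted p = 0.890).

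Of 26 tested cell cycle genes 25 fell and none rose, the same adjusted over the list alone (camera adjusted p = 3.78e-09, adjusted p = 0.0863 with an estimated correlation). Ccnb2, a mitotic cyclin, fell from 5.94 ± 0.558 to 0.448 ± 0.0449 FPKM and Top2a, the topoisomerase of dividing cells, from 6.34 ± 0.495 to 0.765 ± 0.153 FPKM (SD, n = 3 per group).

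Genes of sterol and fatty acid synthesis fell. Of 21 tested genes of cholesterol synthesis and uptake 19 fell and none rose (21 and 0 adjusted over the list alone), with a median log2 fold change of -1.18 (-1.14 and -1.12 within the 2 sets of libraries). Of 14 genes of fatty acid synthesis and desaturation 11 fell and 2 rose, the same adjusted over the list alone. Camera gave an adjusted p = 1.25e-06 for the first and 0.0254 for the second, and with an estimated correlation the adjusted p = 0.0967 and 0.289. Cyp51, an enzyme late in cholesterol synthesis, fell from 16.1 ± 1.37 to 4.25 ± 0.645 FPKM. Fasn, the fatty acid synthase, fell from 12.7 ± 6.003 to 1.76 ± 0.346 FPKM and Mid1ip1, which activates acetyl-CoA carboxylase, from 12.6 ± 6.59 to 2.04 ± 0.595 FPKM (SD, n = 3 per group). The log2 fold change of Fasn was -2.20, and -1.38 after removing the GC and length trend. Within the 2 sets of libraries it was -2.48 and -1.41 for Fasn and -2.22 and -1.18 for Mid1ip1. The 2 that rose, named after their values were seen, were Acss2 (3.74 to 8.72 FPKM), which makes acetyl-CoA from acetate, and Me1 (12.7 to 19.9 FPKM), a source of NADPH.

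Of 22 tested genes of lipid uptake and PPAR targets 9 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.184). Acsl1, which activates long-chain fatty acids, rose from 7.32 ± 0.0825 to 118 ± 6.91 FPKM and Plin2, a coat protein of lipid droplets, from 242 ± 14.5 to 490 ± 20.3 FPKM (log2 fold change 1.02, SE 0.0810, limma adjusted p = 0.000105). Lpl, lipoprotein lipase, fell from 169 ± 12.4 to 33.4 ± 3.43 FPKM. Cd36, a fatty acid receptor, fell from 523 ± 58.3 to 377 ± 37.5 FPKM (limma adjusted p = 0.0142), a call lost without LPS+PA 2, where its log2 fold change was -0.41. Cpt1a, which brings fatty acids into mitochondria, was at 29.8 ± 0.874 and 34.7 ± 1.69 FPKM (log2 fold change 0.21, SE 0.0725, limma adjusted p = 0.0454). This call was lost without any single library other than control 3 (0.18 to 0.25 over all 6 left out in turn) and after quantile normalization (0.11). The Cpt1a call was also lost with no variance trend, without a filter, with the replicate block, with a term for the 2 sets and within each set. After removing the GC and length trend it was kept at 0.51 (limma adjusted p = 0.00312). Of 18 genes of mitochondrial fatty acid oxidation 3 rose and 10 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.175). Acads and Etfb showed the largest falls there, from 9.16 ± 6.08 to 1.13 ± 0.519 FPKM and from 19.1 ± 8.89 to 6.78 ± 1.68 FPKM, but leaving out control 1, control 2, LPS+PA 1 or LPS+PA 2 ended both calls (log2 fold changes from -2.68 to -1.60 for Acads and from -1.73 to -1.04 for Etfb over the 6 libraries left out in turn, and Etfb also lost its call without LPS+PA 3). These falls came mainly from control 1, control 2 and LPS+PA 3 (-2.35 for Acads and -1.52 for Etfb). Within the other 3 libraries the values were -0.88 for Acads and -0.47 for Etfb. Of 13 tested genes of cholesterol efflux and LXR targets 4 rose and 4 fell, the same adjusted over the list alone (median -0.01, camera on the higher side with adjusted p = 0.890). Apoe fell from 1409 ± 846 to 129 ± 66.8 FPKM and Pltp, the phospholipid transfer protein, from 241 ± 57.1 to 62.3 ± 7.43 FPKM. Of 19 tested genes of ceramide and sphingolipid metabolism 3 rose and 9 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.349), among them Sptssa, a subunit of serine palmitoyltransferase (46.2 ± 1.75 to 13.8 ± 1.57 FPKM), and the ceramide kinase Cerk (36.3 ± 8.39 to 14.9 ± 0.942 FPKM).

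**Figure D3:**
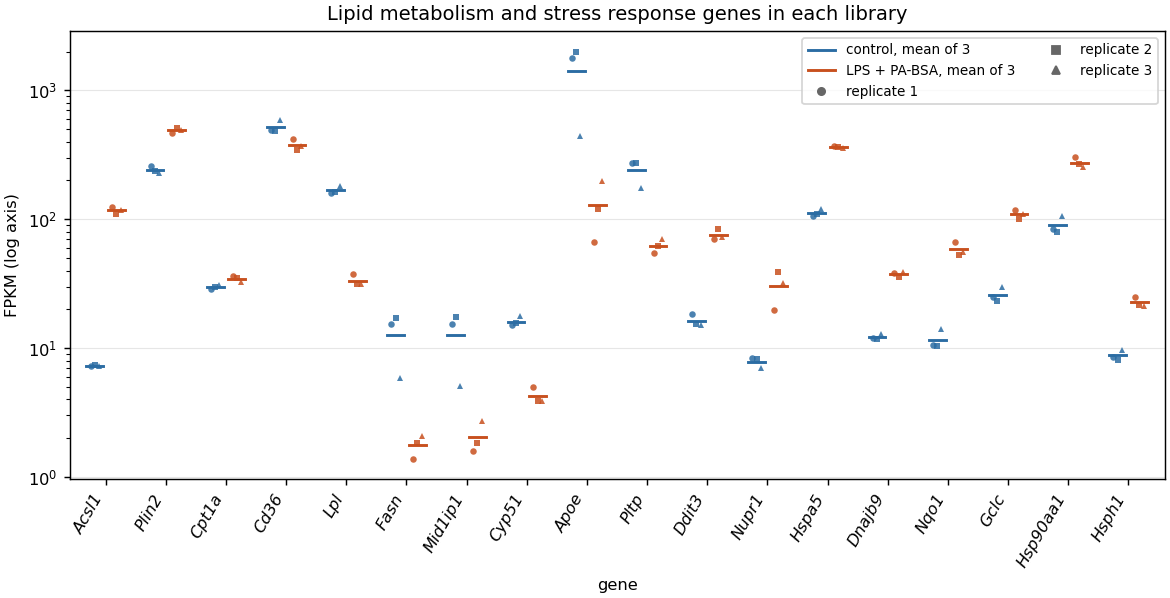
FPKM on a log axis of 18 genes of lipid metabolism and of stress responses in each of the 6 libraries, with 1 point per library (circle, square and triangle for replicates 1 to 3) and a bar at the mean of each group of 3. Acsl1 rose from 7.32 to 118 FPKM, Fasn fell from 12.7 to 1.76, and the stress genes from Ddit3 to Hsph1 lay higher in all 3 LPS + PA-BSA libraries than in all 3 controls.

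Stress response genes rose in 4 of the lists. Of 21 tested ER chaperones and XBP1 targets 16 rose and 1 fell, the same adjusted over the list alone, and Hspa5, the chaperone BiP, went from 112 ± 7.83 to 364 ± 8.39 FPKM (SD, n = 3; log2 fold change 1.69, SE 0.0796, limma adjusted p = 1.28e-05). Dnajb9 rose from 12.2 ± 0.515 to 37.5 ± 1.82 FPKM, and Xbp1 itself was at 32.2 and 33.6 FPKM. The member that fell was Herpud1 (29.1 to 21.8 FPKM). Xbp1 and Herpud1 were named after their values were seen. Of 20 tested genes of the integrated stress response 11 rose and 3 fell, the same adjusted over the list alone. Ddit3, the transcription factor CHOP, rose from 16.3 ± 1.804 to 76.0 ± 7.64 FPKM and Nupr1 from 7.86 ± 0.716 to 30.2 ± 9.73 FPKM. Of 18 genes of the NRF2 antioxidant response 13 rose and 3 fell (13 and 4 adjusted over the list alone), with Nqo1 going from 11.7 ± 2.19 to 58.2 ± 7.05 FPKM and Gclc, the first enzyme of glutathione synthesis, from 26.0 ± 3.43 to 110 ± 8.82 FPKM. The 3 that fell were Cat, Osgin1 and Ftl1, named after their values were seen, and Ftl1 has many pseudogenes that can share its reads. Of 9 tested heat shock genes 8 rose and none fell, the same adjusted over the list alone, with Hsp90aa1 going from 89.7 ± 13.8 to 275 ± 25.9 FPKM and Hsph1 from 8.77 ± 0.861 to 22.6 ± 2.04 FPKM. Camera adjusted p-values were 3.04e-06 for the ER list, 0.00268 for the integrated stress response, 0.000229 for NRF2 and 0.000413 for heat shock, and with an estimated correlation the adjusted p = 0.0812, 0.252, 0.0812 and 0.0967 in that order.

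Of 23 genes of glycolysis and hypoxia 13 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00131, adjusted p = 0.252 with an estimated correlation). Ero1l, an ER oxidase induced by hypoxia, rose from 20.2 ± 2.63 to 54.1 ± 7.63 FPKM and Egln3, a prolyl hydroxylase, from 1.58 ± 0.242 to 5.07 ± 0.370 FPKM. The member that fell was Pdk1 (5.89 to 2.97 FPKM, named after its value was seen). Of 21 tested genes of apoptosis and necroptosis 10 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.00120, adjusted p = 0.112 with an estimated correlation). Those with the largest rises were the antiapoptotic Bcl2a1d (7.13 ± 0.494 to 85.2 ± 7.94 FPKM) and Bcl2a1a (6.63 ± 0.533 to 74.3 ± 11.8 FPKM), near-identical copies whose reads can be split between them. Members of this list that rose thus include inhibitors of cell death. Of 29 genes of oxidative phosphorylation encoded in the nucleus 5 rose and 7 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.890). Cycs, cytochrome c, rose from 16.1 ± 0.733 to 46.6 ± 3.11 FPKM, and Ndufb10 was at 12.96 ± 6.03 and 4.98 ± 1.14 FPKM, a call lost without control 1, control 2, LPS+PA 1 or LPS+PA 2 (log2 fold change -1.50 to -0.83 over the 6 libraries left out in turn). Of 25 tested lysosomal genes 6 rose and 12 fell (6 and 13 adjusted over the list alone; camera adjusted p = 0.395), with the cathepsin gene Ctsz going from 577 ± 28.2 to 1184 ± 61.0 FPKM and Hexa, a hexosaminidase chain, from 368 ± 4.46 to 166 ± 8.09 FPKM. Of 19 autophagy genes 2 rose and 6 fell, the same adjusted over the list alone (median 0.05, mean -0.13, camera adjusted p = 0.847). Of the same genes 7 rose and 5 fell once the GC and length trend was removed (median 0.14, camera adjusted p = 0.637). Ulk1, a kinase that starts autophagy, fell from 7.65 ± 2.02 to 2.74 ± 0.555 FPKM and Map1lc3a from 4.50 ± 1.07 to 1.795 ± 0.664 FPKM (SD, n = 3 per group). After that correction the log2 fold change of Ulk1 went from -1.19 to -0.57 and that of Map1lc3a from -0.98 to -0.29. With a term for the 2 sets besides, Map1lc3a did not pass.

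Markers of other cell types moved with the treatment as well. Of 9 tested fibroblast and stromal genes 8 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00687, adjusted p = 0.252 with an estimated correlation). The collagen genes Col1a1 and Col3a1 fell from 55.3 ± 20.7 to 5.26 ± 1.13 FPKM and from 36.0 ± 12.0 to 3.29 ± 0.337 FPKM, while Dcn, a small proteoglycan named after its value was seen, rose from 4.91 to 23.3 FPKM. Both tested B cell genes fell, the same adjusted over the list alone (camera adjusted p = 0.0146, adjusted p = 0.148 with an estimated correlation, and no longer past the threshold without the filter on low values, at camera adjusted p = 0.339). Ighm, the constant region of the IgM heavy chain, went from 39.1 ± 2.31 to 0.907 ± 0.273 FPKM and Cd79b from 9.48 ± 0.903 to 1.09 ± 0.101 FPKM. Of 5 tested neutrophil genes 3 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.0943, past the threshold at 0.0261 within control 3, LPS+PA 1 and LPS+PA 2). S100a8 rose from 7.39 ± 1.15 to 62.3 ± 4.66 FPKM and Mmp8 from 5.04 ± 0.842 to 9.27 ± 1.63 FPKM. The T and NK cell list had no tested member, and 3 further lists had 1 each. The dendritic cell gene Irf8, also made by macrophages, was at 15.9 ± 3.18 and 9.003 ± 1.22 FPKM (limma adjusted p = 0.00928, and 0.427 once the GC trend was removed). The basophil gene Mcpt8 was at 1.65 ± 0.131 and 1.61 ± 0.723 FPKM (limma adjusted p = 0.821), and the globin gene Hbb-bs at 0.677 ± 0.904 and 2.11 ± 1.96 FPKM (limma adjusted p = 0.332, past the threshold without LPS+PA 3 at a log2 fold change of 1.41).

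All 13 mitochondrially encoded genes fell, the same adjusted over the list alone (camera adjusted p = 6.53e-05, adjusted p = 0.308 with an estimated correlation), among them mt-Cytb from 1125 ± 135 to 473 ± 15.5 FPKM and mt-Nd3 from 59.4 ± 17.1 to 25.2 ± 3.98 FPKM. Their share of all FPKM was 7.20, 7.34 and 9.06% in controls 1 to 3 and 4.83, 4.34 and 4.44% in LPS+PA 1 to 3. The mean share was 7.87 ± 1.03% against 4.54 ± 0.260% (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible). The 10 most abundant genes of each library held 20.1 ± 0.941% of all FPKM in controls and 15.3 ± 0.713% after LPS and PA-BSA, and 11290 ± 73.1 against 10539 ± 82.6 genes reached 1 FPKM (exact permutation test, two-sided p = 0.1 for both, the smallest possible).

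The fold changes followed the GC content of the transcripts. Among the 2271 genes with the lowest GC content (up to 44.8%), 742 were called higher and 422 lower, while among the 2271 with the highest (55.2% or more), 169 were higher and 1147 lower. Across genes, which are not independent replicates, Spearman's rho between GC content and log2 fold change was -0.37. Removing each library's trend also takes out any GC-linked shift that the treated libraries share. Whether that shift is technical or part of the response was not told apart. The median log2 fold change of all tested genes was -0.11 as deposited, -0.01 after median-ratio rescaling and 0.01 after quantile normalization. Calls were tested against no change and not against this median, so their balance moved with the scaling. Of the 6259 calls 40.3% were higher as deposited, 50.9% of 6158 after median-ratio rescaling, 50.8% of 5936 after quantile normalization, and 52.4% of 6819 after removing each library's trend on GC content and length, where 5347 of the calls remained with the same sign and 5 turned. After that removal the counts of higher and lower genes also moved in the lists of the integrated stress response (11 and 3 to 15 and 1), glycolysis and hypoxia (13 and 1 to 17 and 1), apoptosis and necroptosis (10 and 3 to 14 and 2) and lipid uptake and PPAR targets (9 and 6 to 13 and 6). In macrophage identity they moved from 1 and 15 to 1 and 11. All 20 list directions held under these scalings, and the inflammasome and TLR4 lists were those that lost the call under 1 of them.

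**Figure D4:**
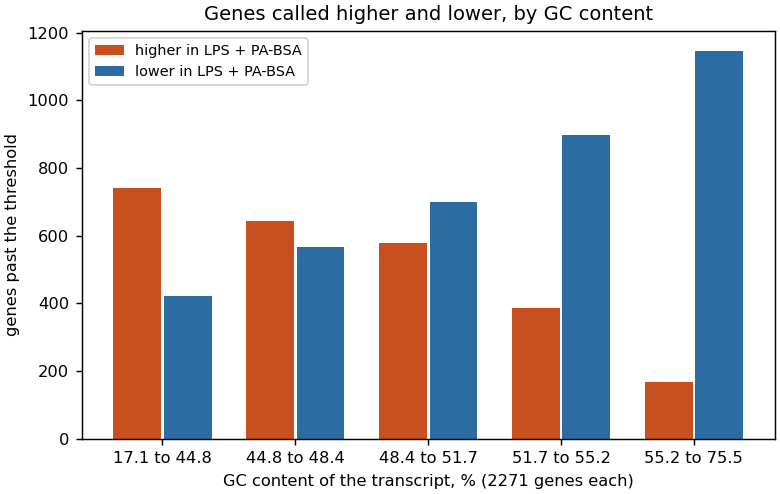
Number of genes past an adjusted p of 0.05 in limma that were higher or lower after LPS + PA-BSA, in 5 bins of 2271 tested genes each, ordered by the GC content of their transcripts in percent. Calls of higher genes fell from 742 to 169 and calls of lower genes rose from 422 to 1147 from the lowest to the highest bin.

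The libraries also fell into 2 sets that cut across the groups. Summed over 26 genes of testis, placenta, epidermis, skeletal muscle and stomach, control 3, LPS+PA 1 and LPS+PA 2 held 71.8, 99.9 and 75.8 FPKM, and control 1, control 2 and LPS+PA 3 held 0.728, 0.959 and 3.85 FPKM. These sets were found from the data, and the labels give no batch. Within control 1, control 2 and LPS+PA 3 alone, limma called 6778 genes (2545 higher), and within control 3, LPS+PA 1 and LPS+PA 2 alone, 2994 (1197 higher), where the lone sample of a group is assumed to vary like the other group. With the set as a term 6511 genes passed (2524 higher). Fold changes of named genes differed between the sets, such as Stab1 (-4.24 and -3.05), Apoe (-3.24 and -2.28), Ndufb10 (-1.22 and -0.55), H2-DMb1 (-1.15 and -0.54) and mt-Nd3 (-0.82 and -1.68). Cd36, Cpt1a, Etfb, H2-DMb1, Il18, Irf8, Mmp8 and Ndufb10 did not pass in the second set, which holds fewer samples. There the log2 fold changes of Cd36 (-0.63), Il18 (0.57) and Cpt1a (0.21) were near or beyond those over all libraries (-0.47, 0.48 and 0.21). Those of Etfb, H2-DMb1, Irf8, Mmp8 and Ndufb10 were smaller in size. Mcpt8 stood at -0.54 in the first set, against -0.06 over all libraries. The authors' deposited table marks 4361 genes as significant, 1424 higher and 2937 lower, all with an absolute log2 fold change of at least 1. Of the 2799 marked genes that were tested here, 2741 were also called here with the same sign. At a q-value under 0.05 alone, without a limit on the fold change as here, the deposited table has 7480 genes, 3609 higher and 3871 lower. Of the 6259 calls here, 5163 had such a q-value and the same sign.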

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

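The removal of the GC and length trend, the set term and the sets alone were tests chosen after seeing the data; the others were planned. Against 6259 genes past the threshold, limma gave 3619 (1891 lower) with a filter at a mean of 5 FPKM, which tests fewer genes, 1993 (756 higher, 1237 lower) with a log2 fold change of at least 1, 4113 (2342 lower) at an adjusted p under 0.01, and 2994 (1197 higher, 1797 lower) in control 3, LPS+PA 1 and LPS+PA 2 alone, which hold fewer samples. The range without single libraries was 4772 to 7051 genes, 2007 to 2778 higher and 2765 to 4273 lower, and between 4732 and 6007 of the calls remained. Median-ratio rescaling, quantile normalization, no variance trend, no filter, both pseudocounts, the GC correction and the set term left the count between 5936 and 6875, but not its balance: 2523 were higher and 3736 lower as deposited, 3134 and 3024 after median-ratio rescaling, 3014 and 2922 after quantile normalization, and 3573 and 3246 after the GC correction, where 5347 of the 6259 calls remained and 5 passed in the opposite direction.

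Of the lists, 20 passed camera with the preset correlation and 0 with an estimated one (10 at an unadjusted p under 0.05; fry, which does not compare a list with other genes, passed 28). Under the other alternatives 15 to 20 passed. At an adjusted p under 0.01 the lists of the inflammasome, the TLR4 pathway, alternative activation, fatty acid synthesis and B cells no longer passed. Alternative activation also missed it with the filter at a mean of 5 FPKM (camera adjusted p = 0.0598), and in control 3, LPS+PA 1 and LPS+PA 2 alone (0.107), where neutrophil markers passed (0.0261). The inflammasome list missed it after the GC correction (0.0542, and 0.0533 with the replicate block), the TLR4 pathway after quantile normalization (0.0944), and B cell markers without a filter (0.339), where fatty acid oxidation passed (0.0443). The causes were not tested. No list and none of the 84 named genes turned direction past the threshold under any alternative, and 8 named genes changed sides without a single library (Acads, Cd36, Cpt1a, Etfb, H2-DMb1, Hbb-bs, Il18 and Ndufb10).

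With the replicate block, 4738 genes passed (1918 higher) and 20 lists. Of the named genes, Cpt1a, Etfb, H2-DMb1, Il18 and Ndufb10 lost their calls with it. Same-numbered libraries' deviations from their group means correlated at -0.47, 0.09 and -0.59 across genes. These values cannot decide whether the replicate numbers pair the samples. The GC trends and the sets of libraries cut across the numbers and could hide a pairing, and the labels do not mention one. With the GC correction and the replicate block 5677 passed. The mitochondrial share differed by -3.33 percentage points, and by -3.20 without the 10 most abundant genes. Small changes can be missed at 3 against 3. On simulated data 22.4% of genes changed by 0.5 on the log2 scale were recovered. That simulation left 11164 of 11364 genes unchanged, so its adjusted threshold was stricter than with the 6259 calls here. The 22.4% is therefore not the share recovered in these data. No simulation varied the depth (13.9 to 21.1 M (mega) fragments).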

Other observations

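Terms of the KEGG annotation in the deposited table, which share genes with each other and with the lists fixed beforehand, were tested too (289 terms, 27 higher and 22 lower by camera with the preset correlation, none with an estimated one, where the lowest adjusted p = 0.276). Tests on these terms, and all tests below marked so, were chosen after the main results were seen; genes named here and below that are not in the report were picked from the tables after their values were seen. Of 43 tested proteasome genes 33 rose and none fell (camera adjusted p = 3.44e-08, adjusted p = 0.347 with an estimated correlation). Beside the immunoproteasome subunit Psmb8 (12.5 ± 1.65 to 43.5 ± 6.56 FPKM), Psmb7, a subunit of the constitutive core, rose from 14.4 ± 1.73 to 37.2 ± 3.38 FPKM (SD, n = 3 per group). Of 69 genes of ribosome biogenesis 34 rose and 3 fell (camera adjusted p = 0.000403, adjusted p = 0.391 with an estimated correlation), with Fcf1 going from 17.3 ± 2.49 to 32.1 ± 1.69 FPKM, whereas of 129 genes of the ribosome itself 12 rose and 60 fell (camera adjusted p = 0.0334, adjusted p = 0.704 with an estimated correlation). The ribosomal genes with the largest falls also spread widely within groups, such as Rps29 at 68.2 ± 39.9 and 9.27 ± 6.74 FPKM, and such genes share reads with pseudogenes.

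In the term valine, leucine and isoleucine degradation 26 of 42 genes fell and 3 rose (camera adjusted p = 0.00882, adjusted p = 0.391 with an estimated correlation), and in butanoate metabolism 10 of 11 fell (camera adjusted p = 0.00556, adjusted p = 0.347 with an estimated correlation). Among the genes with the largest falls in each term, Acads and Aacs count in both, and butanoate metabolism holds Hmgcs1 of the cholesterol synthesis list. Further genes shared by the terms were not counted. Oxct1, which turns ketone bodies into acetyl-CoA, fell from 46.1 ± 4.01 to 15.9 ± 1.69 FPKM and the aldehyde dehydrogenase Aldh2 from 51.7 ± 15.6 to 10.99 ± 2.88 FPKM. Of 15 genes of glycosaminoglycan degradation 12 fell and none rose (camera adjusted p = 0.00703, adjusted p = 0.405 with an estimated correlation), with heparanase, Hpse, going from 75.8 ± 3.39 to 17.8 ± 1.95 FPKM. Beside Ighm and Cd79b, the T cell receptor segment Trav13-4-dv7 (chromosome 14, 53757356 to 53757921 in mm10) fell from 18.6 ± 0.624 to 0.566 ± 0.116 FPKM, while the B cell genes Cd79a, Ms4a1 and Pax5 lay below 0.1 FPKM in the mean of both groups, and the T cell genes Cd3d, Cd3g and Cd8a below 0.03. Why immunoglobulin and receptor transcripts are present without these was not tested.

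Control 3, LPS+PA 1 and LPS+PA 2 held transcripts of tissues other than marrow; the tests of depth and of induction were chosen after the result was seen, that of further lists before. Prm2, of sperm, was at 3.69, 1.497 and 1.64 FPKM and Scgb1a1, of airway, at 0.122, 26.2 and 11.3 FPKM in that order, and both are listed at 0 in the other 3 libraries. Greater depth does not account for it, as the deepest library, control 1, summed to 0.728 FPKM over 26 such genes against 71.8 or more in the 3, nor does induction by the treatment, as LPS+PA 3 summed to 3.85 FPKM, below control 3. Of 11 lists of further tissue genes, 7 reached 1 FPKM in sum and 4 of these (sperm, placenta, epidermis and muscle) had these 3 libraries at the top. These 4 hold further genes of tissues already seen there, so they were no independent test. The other 3 (kidney, liver and further lung genes) did not have these libraries at the top. A lung list could hardly do so, as the lung genes seen before summed to 0.122 FPKM in control 3. The lists of oocyte, brain, intestine and stomach stayed under 1 FPKM. Of these, only the stomach list had the 3 libraries at the top (0.0810 to 0.208 FPKM). RNA or reads of other tissues thus stay an open explanation. Of the 84 tissue genes in the table, 52 reached 0.5 FPKM in any of control 3, LPS+PA 1 and LPS+PA 2. In the other 3 libraries 11 did. The 84 include the genes by which the libraries were told apart. Among the 11 were Odf2 and Napsa, which lay at similar levels in all libraries. Kidney's Kap was at 4.46 FPKM in control 2 and 1.55 in LPS+PA 3 and listed at 0 in the other 4.

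Control 3 and LPS+PA 1 departed from their groups in the same genes, and the tests were set before the values were seen. Across 11364 genes, which are not independent replicates, the departure of control 3 from controls 1 and 2 correlated with that of LPS+PA 1 from LPS+PA 2 and 3 at 0.60. The departures followed GC content (rho -0.68 and -0.61), but after removing each library's trend on GC and length the correlation was still 0.42, so GC content is not the whole of it. The departure of control 3 also correlated with the difference of LPS+PA 2 from LPS+PA 3, at 0.34 after that correction. That value depends on LPS+PA 3 as much as on LPS+PA 2. With departures from the group mean the correlation was -0.47 for LPS+PA 3 and 0.04 for LPS+PA 2 (-0.14 before correction). The GC trend of LPS+PA 2 ran the other way (rho 0.39). Departures from a group mean cancel out within the group, so the large one of LPS+PA 1 pushes the others the other way. The values of LPS+PA 2 therefore cannot weigh against its belonging with control 3. Whether LPS+PA 2 belongs with control 3 and LPS+PA 1 in a set of cultures or libraries beyond the transcripts of other tissues thus stays open. Retnla and Chil3, markers of alternative activation, were at 19.5 and 6.800 FPKM or more in control 1, control 2 and LPS+PA 3 and below 0.6 in the other 3; cultures, animals and preparations were not told apart.

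The stromal fall was weighed against technical explanations; the tests of the sets and of cell share were chosen after the result was seen, that of GC before. It held within both sets of libraries, where the higher of the 2 medians was -1.34. After the GC and length correction the median was -1.40. Camera then gave an adjusted p = 0.00353 with the preset correlation and 0.188 with an estimated one, which did not pass. The 9 tested members spread over 5.16 on the log2 scale, from -3.11 for Col1a1 to 2.05 for Dcn, more than their errors. On log2(FPKM + 1) low genes move less, so unequal falls cannot tell a smaller share of stromal cells from other changes. A smaller share alone would not raise a member, as seen for Dcn only. A change of expression in stromal cells, in macrophages or in both, with or without a change in share, may account for it and was not told apart here.

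With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 6259 genes past the threshold in limma, the highest of the other 9 gave 0 (24 to 820 genes at an unadjusted p under 0.05), and 1 of 10 splits, the real one, gave as many. For lists the real split gave 20 by camera and the highest other 18, and 1 of 10 splits gave as many. Each other split sets 2 libraries of a group against 1, so part of the treatment difference remains between its sides. The rest lies within each side, where it widens the spread and holds limma calls down. The counts of these splits, the 0 included, are therefore not values without treatment, and 6259 against 0 does not measure chance.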
